A study of Mus musculus with 14 samples.

How the data were processed

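The series holds 14 mouse hippocampus libraries, 4 of RNA-seq and 10 of ChIP-seq or its input. Samples were grouped by the genotype, antibody and age in the submitters' labels. RNA was extracted with Trizol and treated with DNase I, and chromatin was fixed with disuccinimidyl glutarate and formaldehyde before HDAC3 immunoprecipitation, per the labels' protocols. TopHat, Bowtie, Cufflinks 2.0.0, Cuffdiff, BWA, SAMtools, bedtools and, for the 12-week samples, the build mm9 are named in the submitters' processing notes, which give no role or order. The annotation, the selection of RNA before library preparation and the strand setting are not given in the sources used here.

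The authors deposited expression as FPKM per gene and library for 22548 genes, per the file headers and the submitters' processing notes. FPKM divides by gene length, so a single read on a gene shorter than a fragment becomes a large value. The authors' deposited table of the comparison gives group FPKM, a log2 fold change and an unadjusted p-value for each listed gene, per the file headers, and the number of genes tested is not given there. The deposited HDAC3 peak list gives for each peak a maximum score, a −log10 p, a normalised tag count (a whole-number signal from 0 to 17) and a false discovery rate in percent, per the file headers. What the signal was normalised to, which libraries were combined, which control was used and the settings of the peak caller are not given in the sources used here. The deposited peak list carries the word dfilter in its name, which may stand for the peak caller DFilter. The score is the authors' own and was used only to rank and filter peaks. Peak coordinates were converted to 1-based starts in mm9.

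The unit required another test than a count model. Genes with a mean of at least 1 FPKM over the 4 libraries (11651) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the prior variance, a two-sided test and Benjamini-Hochberg adjustment at 0.05, for 2 knockout against 2 wild-type libraries with no covariate. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists were fixed before the data were examined, 38 in all, each with at least 3 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 38 lists. They were tested again with an estimated correlation and with fry. With an estimated correlation, camera rests on the few residual degrees of freedom of 2 against 2 libraries, so a list can hardly pass whatever its correlation. Members were adjusted over all genes and over the list alone. Lists shared members, such as Npy and Sst between neuropeptides and interneuron markers.

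Gene classes were taken by symbol or synonym from RefSeq for GRCm38, which matched 22340 of 22548 symbols. By class, or by name where RefSeq had no match, 727 genes were short RNA genes, 288 of them among the genes tested. RefSeq was used for names, classes and neighbours only, since its build differs from mm9. The value of 1 read was estimated from ratios of low values between libraries. For named genes the rule, fixed at the same time as the lists, took Hdac3, Mecp2, Ncor1, Ncor2, Foxo1, Foxo3 and Foxo6, up to 12 genes per direction with the largest change past the limma threshold and separated replicates, and up to 4 members with the largest change per list. Where fewer than 12 passed, genes of the authors' table with the largest change, a mean of at least 1 FPKM and separated replicates would complete the 12. Since the limma genes were nearly all short RNA genes, that last part was applied after leaving these out, a choice made after seeing the data.

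The planned test of HDAC3 peaks at start sites against all expressed genes, and the planned shift in fold change of peak genes, need gene positions in mm9 for all genes, which were not at hand. In their place, the loci of the authors' deposited table were used, with a peak within 1 kb of either locus end. Genes listed higher were compared with genes listed lower by a two-sided Fisher's exact test, and by its exact stratified form within tertiles of mean FPKM or locus length. Peaks were also moved 100 times by random distances along each chromosome. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

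The limma step was tested on simulated data with 2 against 2 libraries and 200 changed genes. With all genes, 77% of genes changed by 1 on the log2 scale and 95% of genes changed by 2 were recovered among 11548 genes, with 8 false calls. Without short RNA genes these shares were 95% and 100% among 11272 genes, with 4 false calls. Changes were planted only in genes with a mean above 2 on the log2(FPKM + 1) scale. Recovery of lower genes, and of changes below 1, was therefore not measured. The simulation draws independent errors and knows no library that stands apart, so real recovery can be lower. Its 200 planted changes also loosen the Benjamini-Hochberg cut-off, which is stricter where few genes change, so these shares do not carry over to the real data. In the real data without short RNA genes, Wfs1 had a log2 fold change of -1.01 and did not pass (limma adjusted p = 0.345). Each result was repeated with other pseudocounts (0.1 and 0.5), filters (none and 5 FPKM), scalings, variance priors and thresholds, a replicate block, each library left out, stricter peaks and other peak windows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.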

Results

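The series profiled mouse hippocampus at 2 levels. RNA-seq was made from wild-type mice (2 libraries) and from mice with a conditional knockout of Hdac3 (2 libraries), all 12 weeks old and on the C57BL/6J background. Hdac3 encodes a class I histone deacetylase, the enzyme that acts within the NCoR and SMRT corepressor complexes. ChIP-seq with an antibody against HDAC3 was made from wild-type hippocampus (3 libraries, with 3 input libraries). At postnatal day 45, 1 HDAC3 and 1 input library were made from wild-type mice, and 1 of each from mice lacking Mecp2, which encodes a methyl-CpG-binding protein. The series title joins HDAC3 with MeCP2 and the FoxO transcription factors in behaviours related to autism. Gene expression per RNA library, the authors' table of differing genes and a combined HDAC3 peak list were analysed, so the wild-type and Mecp2 knockout ChIP libraries were not compared here. The labels do not state whether the 2 libraries of a genotype came from separate mice. Limma's tests of single genes then measure only the spread between these libraries. Camera at the preset correlation sets the members of a list against the other genes, and does not measure how a list varies between libraries. A shift carried by 1 library can thus give a low camera p. Fry, which uses the spread between libraries, called no list in one direction (lowest adjusted p = 0.395).

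Summed FPKM lay between 314943 and 325643 per RNA library, of which short RNA genes (microRNAs, snoRNAs and similar) held 57.8% to 60.4%. The values of the lowest genes fell into steps of what 1 read is worth, and by these steps the depth of the 4 libraries lay between 97.6% and 100% of that of wild-type library 1. The absolute depth is unknown. Without short RNA genes, the 2 wild-type libraries correlated at r = 0.988 across genes and the 2 knockout libraries at r = 0.984, while wild-type library 2 and knockout library 2 correlated at r = 0.992. With short RNA genes the 2 pairs within a genotype correlated highest (r = 0.941 and 0.940), so grouping by genotype held with these genes and not without them. These correlations are across genes, which are not independent replicates.

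The targeted gene came first. Hdac3 stood at 14.5 and 14.2 FPKM in the wild-type libraries and at 13 and 13.4 FPKM in the libraries labelled Hdac3 knockout. Both knockout libraries were lower, with 13.2 ± 0.313 FPKM (SD, n = 2) against 14.4 ± 0.168 FPKM (SD, n = 2) and a log2 fold change of -0.11 (SE 0.0656, limma adjusted p = 0.729). A conditional deletion leaves reads from cells without it and from exons outside it, so a value for the whole gene in whole tissue is a weak check of these labels. None of the partners of HDAC3 or the factors of the series title passed. Mecp2 was higher in both knockout libraries, as were the corepressor subunit genes Tbl1xr1 (8.34 and 7.74 against 9.05 and 8.64 FPKM) and Tbl1x (6.13 and 6.60 against 7.19 and 6.76 FPKM). Ncor1 had 15.8 ± 0.276 FPKM in wild type and 16.7 ± 2.40 FPKM in knockout, Ncor2 had 5.98 ± 0.349 and 5.69 ± 0.237 FPKM, and Mecp2 had 8.08 ± 0.182 and 8.54 ± 0.101 FPKM (SD, n = 2). Foxo1 had 1.55 ± 0.159 and 1.57 ± 0.0974 FPKM, Foxo3 had 4.37 ± 0.0735 and 4.27 ± 0.221 FPKM, and Foxo6 had 3.23 ± 0.292 and 3.02 ± 0.720 FPKM (SD, n = 2). Among the 6 genes from Ncor1 to Foxo6 the lowest limma adjusted p was 0.788, for Mecp2, and that of Tbl1xr1 was 0.728. The Ncor1, Foxo1, Foxo3 and Foxo6 differences changed sign under at least 1 other setting.

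The question of the RNA-seq was which hippocampal genes depend on Hdac3. Immediate early genes, the activity-induced transcription factors and synaptic effectors of neurons, fell as a list in the knockout. Of 20 measured members, 18 were lower, with a median log2 fold change of -0.38 (camera adjusted p = 4.48e-06; adjusted p = 0.871 with an estimated correlation). None of the 20 passed over all genes tested, and 8 passed when adjusted over the list alone, 7 of them lower. Arc, a postsynaptic regulator of AMPA receptors, had 33.5 ± 2.58 FPKM in wild type and 17.7 ± 1.33 FPKM in knockout (SD, n = 2; log2 fold change -0.89, SE 0.0964, adjusted p = 0.109 over all genes and 0.00895 adjusted over the list alone). Nr4a1, an orphan nuclear receptor, had 9.03 ± 0.999 against 5.36 ± 0.510 FPKM (SD, n = 2). The MAP kinase phosphatase gene Dusp5 had 6.93 ± 1.31 against 4.06 ± 0.633 FPKM, and the neuronal pentraxin gene Nptx2 had 6.17 ± 0.0896 against 3.78 ± 0.771 FPKM (SD, n = 2). These 3 also passed when adjusted over the list alone. Jun, named after its value was seen because it was the passing member that went the other way, had 4.33 ± 0.188 FPKM in wild type and 6.33 ± 0.345 FPKM in knockout (SD, n = 2).

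Neuropeptide genes fell as a list too, with 11 of 12 members lower and a median log2 fold change of -0.44 (camera adjusted p = 0.00494; adjusted p = 0.871 with an estimated correlation). None passed over all genes and 2 passed when adjusted over the list alone. These were Cck (cholecystokinin), with 155 ± 10.9 FPKM in wild type and 105 ± 0.378 FPKM in knockout, and Npy (neuropeptide Y), with 25.9 ± 0.735 against 17.4 ± 2.40 FPKM (SD, n = 2). Nts (neurotensin) had 3.34 ± 1.35 against 1.69 ± 0.536 FPKM and Penk (proenkephalin) had 4.92 ± 1.63 against 3.11 ± 0.655 FPKM (SD, n = 2), neither past a threshold. The list's call was lost without knockout library 1 (median -0.32, adjusted p = 0.0567) and without a filter on low values (median -0.24, adjusted p = 0.0875), and the adjusted p over its 15 alternatives lay between 5.31e-08 and 0.0875. Without wild-type library 2 its median was -0.29. Markers of neighbouring regions did not pass but were lower for 4 of 5 thalamic members (median -0.42, adjusted p = 0.250) and 4 of 5 striatal members (median -0.20, adjusted p = 0.703), with Penk and Tac1 on both the striatal and the neuropeptide list. The authors' deposited table lists 3 thalamic markers as lower, Plekhg1, Prkcd and Slc17a6.

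Marker genes of CA1, a hippocampal field of pyramidal neurons, were lower for 8 of 9 members, with a median log2 fold change of -0.30 (camera adjusted p = 0.0211; adjusted p = 0.871 with an estimated correlation). None passed over all genes and 3 passed when adjusted over the list alone. Wfs1, which encodes an endoplasmic reticulum membrane protein, had 14.7 ± 0.429 FPKM in wild type and 6.91 ± 2.01 FPKM in knockout (SD, n = 2), and Lefty1 had 3.86 ± 0.354 against 2.69 ± 0.344 FPKM (SD, n = 2). Fibcd1 had 17.6 ± 1.54 against 12.6 ± 4.24 FPKM (SD, n = 2), and Nov had 29.4 and 32.9 FPKM in wild type but 14.2 and 30.2 FPKM in the 2 knockout libraries. The list missed the threshold without wild-type library 2 (adjusted p = 0.0749), without knockout library 1 (median -0.14, adjusted p = 0.0567) and over genes with a mean of at least 5 FPKM (adjusted p = 0.0547), and its adjusted p over 15 alternatives lay between 2.65e-05 and 0.0749. Markers of CA3 (median -0.04, adjusted p = 0.781) and of the dentate gyrus (median 0.01, adjusted p = 0.781) did not pass. Markers of oligodendrocyte precursors were lower for 7 of 7 members with a median of -0.16 (camera adjusted p = 0.0269; adjusted p = 0.871 with an estimated correlation), none of them past the threshold over all genes or adjusted over the list alone. Gpr17 had 5.02 ± 0.287 against 4.03 ± 0.339 FPKM, Olig1 had 11.1 ± 0.735 against 9.47 ± 0.2 FPKM, Olig2 had 3.06 ± 0.529 against 2.58 ± 0.164 FPKM, and Pdgfra had 4.6 ± 0.00369 against 4.01 ± 0.0228 FPKM (SD, n = 2). This list missed the threshold whichever of the 4 libraries was left out, with adjusted p between 0.0523 and 0.165, and in 2 other settings. Over its 14 alternatives the adjusted p lay between 0.00396 and 0.165.

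Cholesterol synthesis genes rose as a list, with 18 of 20 members higher and a median log2 fold change of 0.18 (camera adjusted p = 1.32e-06; adjusted p = 0.871 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Insig1, the sterol-regulated anchor of SCAP, had 8.92 ± 1.26 FPKM in wild type and 12.2 ± 1.75 FPKM in knockout, and Sqle (squalene epoxidase) had 5.93 ± 0.507 against 7.81 ± 0.474 FPKM (SD, n = 2). Fdft1 (squalene synthase) had 8.52 ± 0.694 against 11.5 ± 1.65 FPKM, and Sc4mol had 12.7 ± 0.333 against 16.2 ± 2.22 FPKM (SD, n = 2). The list median was 0.11 without wild-type library 2 and 0.11 without knockout library 1, with the call kept in both.

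Genes of the presynaptic release machinery rose as a list, with 17 of 20 members higher and a median of 0.15 (camera adjusted p = 7.84e-06; adjusted p = 0.871 with an estimated correlation). None passed over all genes and 2 passed when adjusted over the list alone. Snap25, a SNARE protein of synaptic vesicle fusion, had 244 ± 20.5 FPKM in wild type and 388 ± 30.8 FPKM in knockout, and Syn1 (synapsin I) had 18.2 ± 0.149 against 26.4 ± 0.928 FPKM (SD, n = 2). Cplx2 (complexin 2) had 73.0 ± 3.98 against 90.4 ± 10.4 FPKM and Bsn (bassoon) had 16.6 ± 0.308 against 20.3 ± 1.52 FPKM (SD, n = 2). The median was 0.07 without knockout library 1, with the call kept. Circadian clock genes rose as a list, with 11 of 16 members higher and a median of 0.13 (camera adjusted p = 0.00151; adjusted p = 0.871 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Gm129, a clock repressor also called Ciart, had 3.42 ± 0.102 against 5.12 ± 0.676 FPKM, and Dbp, a D-box binding factor, had 12.6 ± 0.625 against 15.8 ± 0.0996 FPKM (SD, n = 2). Hlf had 6.55 ± 1.57 against 8.74 ± 0.297 FPKM and Nr1d1 (Rev-erb alpha, which recruits NCoR and HDAC3) had 12.9 ± 0.604 against 16.7 ± 3.30 FPKM (SD, n = 2). The clock median was 0.04 without wild-type library 1 and 0.20 without wild-type library 2, with the call kept in both.

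**Figure D1:**
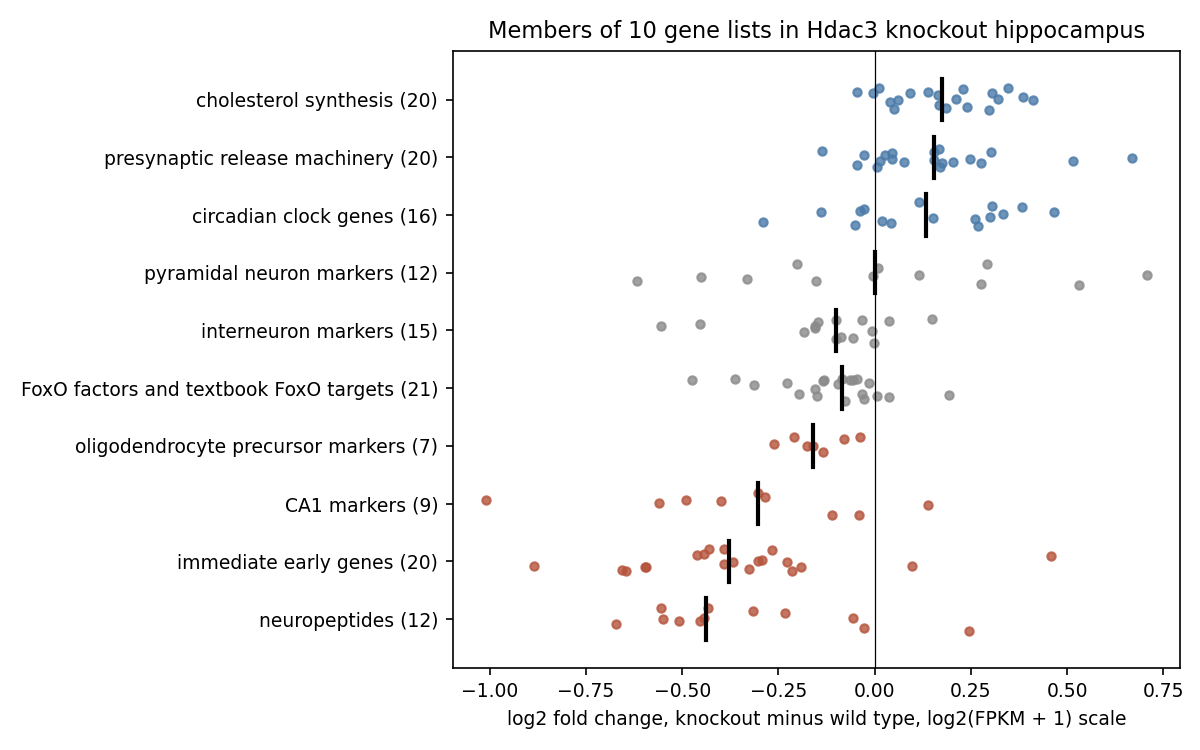
Each point is a member of 1 of 10 gene lists, placed by its log2 fold change (knockout minus wild type, on the log2(FPKM + 1) scale, 2 libraries each), and black bars mark list medians; the number of measured members stands in parentheses. Blue marks lists that rose, red lists that fell and grey lists that did not pass; medians ran from 0.18 for cholesterol synthesis to -0.44 for neuropeptides.

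The other 31 lists did not pass, with adjusted p between 0.154 and 0.998. FoxO factors and their textbook targets had a median log2 fold change of -0.08, with 18 of 21 members lower (camera adjusted p = 0.225), none past the threshold over all genes or adjusted over the list alone. Among them Txnip, a thioredoxin inhibitor, had 4.82 ± 0.573 FPKM in wild type and 3.18 ± 0.254 FPKM in knockout, Gadd45a had 1.33 ± 0.222 against 0.816 ± 0.223 FPKM, and Ccng2 had 7.84 ± 0.161 against 6.57 ± 0.733 FPKM (SD, n = 2). Tsc22d3 had 12.6 and 27.2 FPKM in the wild-type libraries and 12.3 and 17.6 FPKM in the knockout libraries. The HDAC3 corepressor complex had a median of 0.03 over 6 members (adjusted p = 0.703), which was -0.05 without knockout library 1. In these 31 lists no member passed over all genes, and adjusted over the list alone 2 pyramidal neuron markers and 1 thalamic marker passed, all lower.

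Pyramidal neuron markers had a median of 0.00 (adjusted p = 0.995), but their members moved apart. Nptx1 had 28.7 and 27.7 FPKM in wild type and 59.1 and 36.7 FPKM in knockout, and Nrgn (neurogranin) had 114 ± 9.71 against 174 ± 79.1 FPKM (SD, n = 2). Neurod6, a transcription factor of pyramidal neurons, had 32.1 ± 2.43 against 20.6 ± 1.04 FPKM and the potassium channel gene Kcnv1 had 4.97 ± 0.446 against 3.36 ± 0.149 FPKM (SD, n = 2), and these 2 passed when adjusted over the list alone. The pyramidal median was 0.24 in knockout library 1 and -0.28 in knockout library 2, each set against the wild-type mean. Without knockout library 2 the list passed (adjusted p = 0.0209), and over its 15 alternatives the adjusted p lay between 0.0209 and 0.996. Interneuron markers had a median of -0.10 (adjusted p = 0.256), which was -0.20 without knockout library 2 (adjusted p = 0.000957) and 0.03 without knockout library 1, with an adjusted p between 0.000957 and 0.658 over 15 alternatives. Astrocyte markers had a median of -0.06 (adjusted p = 0.998), microglia markers 0.02 (adjusted p = 0.391), oligodendrocyte markers -0.02 (adjusted p = 0.995) and endothelial markers -0.05 (adjusted p = 0.703). Meningeal fibroblast markers had a median of 0.25, with 3 of 3 members higher (adjusted p = 0.235).

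**Figure D2:**
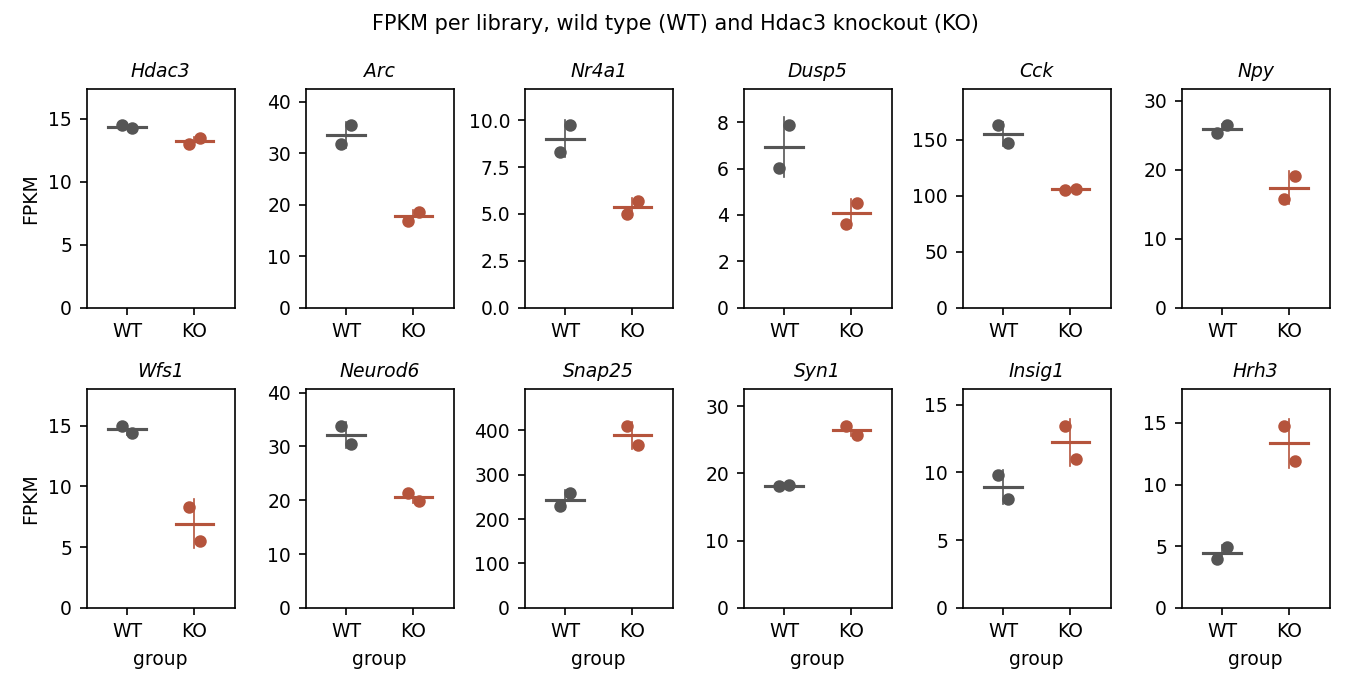
FPKM (linear axes from 0) of 12 genes in the 2 wild-type (WT, grey) and 2 Hdac3 knockout (KO, red) libraries; points are libraries, horizontal bars group means and vertical lines SD. Hdac3 had 14.4 FPKM in wild type and 13.2 FPKM in knockout, while Hrh3 had 4.44 and 13.4 FPKM. In each of the 12 genes both knockout libraries lay on the same side of both wild-type libraries. The 12 are a choice among the named genes, and named genes with overlapping replicates, such as Nov and Nrgn, are not shown.

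At the level of single genes, 38 of 11651 tested genes passed the limma threshold, 19 higher and 19 lower in the knockout. Of these 37 were short RNA genes, and 17 of the 38 were listed at 0 in both libraries of a group. The 12 higher genes with the largest change were Snord70, Mir99a, Snord61, Snord87, Mir154, Mir125a, Mir381, Mir654, Mir5103, Mir128-2, Mir1930 and Mir5128. The 12 lower ones were Scarna9, Snord100, Mir30a, Mir3066, Mir1900, Snord23, Mir493, Mir338, Mirlet7b, Mir697, Mirlet7c-2 and Mir323. Mir30a was listed at 61.7 and 62.8 FPKM in wild type and at 0 in both knockout libraries, and Mir99a at 0 in both wild-type libraries and at 293 and 191 FPKM in knockout. All of these are uncertain, since 1 read on so short a gene can be worth many FPKM. The remaining call was G530011O06Rik, a long non-coding RNA gene that lies within Mid1 in RefSeq on the X chromosome. It had 24.4 ± 1.29 FPKM in wild type and 1.65 ± 0.384 FPKM in knockout (SD, n = 2; log2 fold change -3.26, SE 0.122, adjusted p = 0.00258) and is uncertain as an overlapping gene. The count of higher genes was 58 without knockout library 1 and 30 without knockout library 2, and that of lower genes was 43 without wild-type library 1.

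Without short RNA genes, a setting chosen after seeing the data, 11363 genes were tested. Limma without a replicate block called 0 of them higher and 1 lower, G530011O06Rik. At an unadjusted p under 0.05, 280 were higher and 644 lower. With the replicate number as a block, described below, limma called 87 higher and 186 lower, but the labels do not say that a number marks a pair. Without short RNA genes and without the block, the 7 lists above passed camera again with the preset correlation. None passed with an estimated correlation (camera adjusted p = 0.715) or with fry in one direction (lowest adjusted p = 0.297). The estimated correlation was -0.11 for CA1 markers and -0.14 for oligodendrocyte precursor markers, below the preset, and these calls were lost too. The loss alone is therefore no evidence that correlation among members made the calls. For the other lists that passed, the estimated correlation was above the preset. It was 0.079 for neuropeptides, 0.10 for immediate early genes, 0.17 for clock genes, 0.20 for presynaptic genes and 0.30 for cholesterol synthesis. If these estimates hold, the camera p-values at the preset are too low for these lists. Fry for change in either direction passed for the CA1 markers (adjusted p = 0.00313, or 0.00653 with short RNA genes). Without short RNA genes, 12 immediate early genes passed lower and 1 higher when adjusted over the list alone, and 3 clock genes passed higher. In lists that did not pass, 1 GABA-A subunit, 1 potassium channel and 1 interneuron marker then also passed lower, and 1 endoplasmic reticulum stress gene higher. Both knockout libraries lay on one side of both wild-type libraries for 39.8% of the 11363 genes, where chance gives 33.3%. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so no single gene was tested that way.

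The authors' deposited table lists 303 genes at an unadjusted p under 0.05, 109 higher and 194 lower in the knockout. In 267 of them (88.1%) both knockout libraries lay on the stated side of both wild-type libraries. Chance gives 16.7% for genes that were not selected. The listed genes were selected for a difference between the same libraries, which favours separation, so 16.7% is no benchmark for them. Only 21 of the authors' deposited p-values would pass a Benjamini-Hochberg adjustment over 11651 genes. That number counts genes with a mean of at least 1 FPKM, which 243 of the 303 reached, and the authors' own number of tested genes is not given. Among listed genes with a mean of at least 1 FPKM and separated replicates, short RNA genes left out after seeing the data, Hrh3 led the higher genes of the authors' deposited table with a log2 fold change of 1.63. Hrh3, the histamine H3 receptor, had 4.44 ± 0.651 FPKM in wild type and 13.4 ± 2.01 FPKM in knockout (SD, n = 2; limma adjusted p = 0.167 without short RNA genes). The others were Gm7120, Gm14378, Scn4b, Ppp1r1b, Acvr1c, Hspb8, Hr, Nptx1, Dcn, Cdk5r2 and Nlrx1, with log2 fold changes between 0.77 and 1.34 in the authors' deposited table. Scn4b, a sodium channel beta subunit, stood at 2.97 and 3.20 FPKM in wild type and at 9.86 and 3.76 FPKM in knockout, and Ppp1r1b (DARPP-32) at 3.54 and 3.40 against 10.2 and 4.22 FPKM, so knockout library 1 set most of both differences. For 7 of these 12 genes, 1 library left out lowered the log2 change by over 1.5 times: knockout library 1 for Scn4b, Ppp1r1b, Acvr1c, Nptx1 and Cdk5r2, knockout library 2 for Dcn and wild-type library 1 for Gm7120.

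With the same limits on mean FPKM and replicates, the 12 lower genes with the largest change in the authors' deposited table were G530011O06Rik, Wnt2, Grem1, Xdh, 1700007F19Rik, Stac, Spink8, Wfs1, Doc2b, Htr5b, Nts and Ly6a, with log2 fold changes between -3.92 and -0.98. The same held for 5 of the 12, with wild-type library 2 left out for Xdh, Ly6a, Nts and Htr5b, knockout library 1 for Htr5b, and wild-type library 1 or knockout library 2 for 1700007F19Rik. Xdh (xanthine dehydrogenase) stood at 0.780 and 2.31 FPKM in wild type and at 0.650 and 0.577 FPKM in knockout, and Ly6a at 6.15 and 12.3 against 4.46 and 5.02 FPKM. Wnt2, a secreted Wnt ligand, had 2.11 ± 0.164 FPKM in wild type and 0.592 ± 0.110 FPKM in knockout, and Grem1, a BMP antagonist, had 1.68 ± 0.577 against 0.485 ± 0.00831 FPKM (SD, n = 2). Spink8 had 19.6 ± 1.31 against 9.37 ± 1.49 FPKM and Doc2b, a calcium sensor of vesicle release, had 7.27 ± 0.588 against 3.46 ± 0.455 FPKM (SD, n = 2). By the fixed lists, the authors' deposited table held 9 immediate early genes (8 lower), 6 neuropeptide genes (6 lower), 3 CA1 markers (3 lower) and 2 presynaptic genes (2 higher). It did not list Hdac3.

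The combined HDAC3 peak list asked where the deacetylase lies on chromatin. It held 6150 peaks with a median width of 450 bp (25 to 11025 bp), 621 of them on chromosome 11, 45 on X and 0 on Y. The authors' score had a median of 279, and 3454 peaks had a false discovery rate under 1% in the authors' file. A value of at least 10 on the authors' −log10 p scale was reached by 249 peaks. In mm9 coordinates the 5 highest-scoring peaks lay on chromosome 17 at 24300083 to 24301357 (the highest score), chromosome 6 at 116157380 to 116158729 (score 1699), chromosome 9 at 59386897 to 59388146 (score 1617), chromosome 9 at 21171497 to 21172946 (score 1579) and chromosome 2 at 164658559 to 164660008 (score 1505). Gene positions of that build were at hand only for the genes of the authors' deposited table, so the peaks as a whole were not annotated. The list is combined and carries no replicate spread.

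HDAC3 peaks lay at genes listed higher more often than at genes listed lower. A peak within 1 kb of either end of the locus was found for 37 of 109 higher genes (33.9%, exact 95% interval 25.1% to 43.6%) and for 28 of 194 lower genes (14.4%, 9.81% to 20.2%), with an odds ratio of 3.03 (95% interval 1.67 to 5.58, two-sided Fisher's exact p = 1.25e-04). Peaks moved by random distances along their chromosomes met 1.2% and 1.34% of these genes on average. Moved peaks fall anywhere along a chromosome, so these shares do not tell whether listed genes carry more peaks than other expressed genes, which was not compared. The higher genes were also more strongly expressed, with a median of 8.59 FPKM against 3.46 FPKM, and had shorter loci, with a median of 15 kb against 30.7 kb. Within tertiles of mean FPKM the pooled odds ratio was 2.39 (95% interval 1.24 to 4.63, exact stratified p = 0.00680). It did not pass in the lowest tertile (odds ratio 3.97, Fisher's exact p = 0.141) or the middle tertile (odds ratio 1.37, Fisher's exact p = 0.572). Strand is not given in the table, so either end of a locus stood in for the start site, and 2 of the 65 genes with a peak shared it with each other.

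Several of the genes named above carried such a peak. Among genes listed lower, a peak lay at Arc (chromosome 15, 74502558 to 74503282, score 302), Nr4a1 (chromosome 15, 101096683 to 101097432, score 308), Dusp5 (chromosome 19, 53602833 to 53603257, score 274), Cck (chromosome 9, 121404322 to 121404771, score 287) and Wfs1 (chromosome 5, 37380592 to 37380616, score 253, among the weakest of the list). Among genes listed higher, a peak lay at Nr1d1 (the strongest of 3 on chromosome 11, 98634029 to 98637178, score 438), Nptx1 (chromosome 11, 119407104 to 119409003, score 314), Insig1 (chromosome 5, 28398117 to 28398866, score 274), Ppp1r1b (chromosome 11, 98220004 to 98220278, score 268) and Jun, with 2 peaks (the stronger on chromosome 4, 94715752 to 94716101, score 280). The peaks given here at Dusp5, Wfs1, Insig1 and Ppp1r1b scored below the list median and missed a false discovery rate under 1%. Those at Dusp5, Wfs1 and Ppp1r1b lay outside the locus, within 1 kb of its end. Of the 9 immediate early genes in the authors' deposited table, 6 had a peak, against 1 of 6 neuropeptide genes and 0 of 2 presynaptic genes. These shares were not tested against each other.

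**Figure D3:**
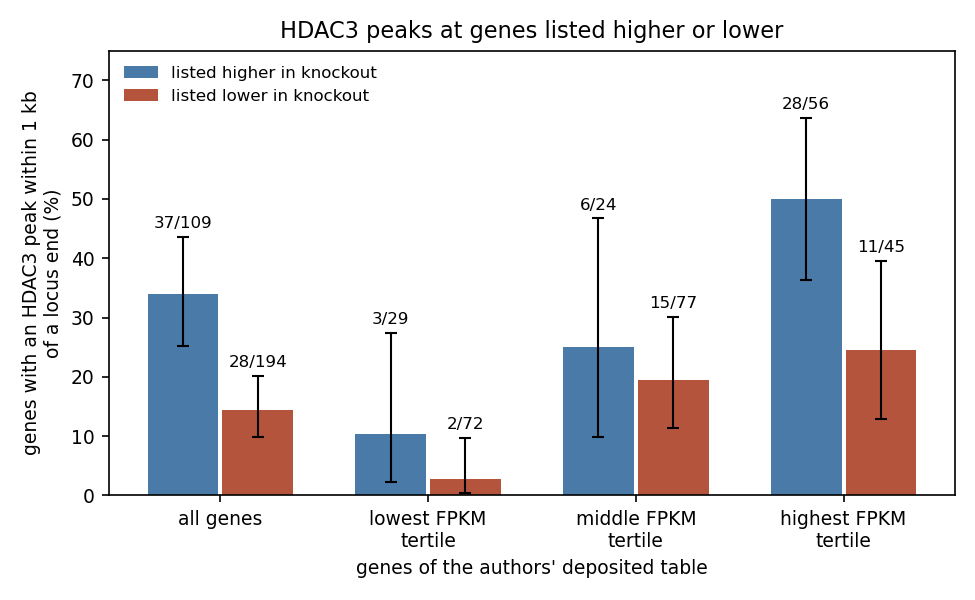
Percent of genes of the authors' deposited table with an HDAC3 peak within 1 kb of either locus end, for genes listed higher (blue) and lower (red) in the knockout, over all genes and within tertiles of mean FPKM; error bars are exact 95% binomial intervals and labels give genes with a peak over genes listed. The share was 33.9% for higher and 14.4% for lower genes over all genes, and 50% against 24.4% in the highest tertile.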

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

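The settings without short RNA genes, the false discovery rate limit on peaks, the locus length tertiles and the limits on listed genes in the peak comparison were chosen after seeing the data. Hdac3 kept its direction and stayed short of the threshold in all 15 alternatives. Leaving out a library leaves 1 sample in a group, which limma then assumes to vary like the other group.

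The count of genes higher in the knockout was 19 and became 60 without a filter on low values, and between 13 and 58 with 1 library left out. The count of lower genes was 19 and became 9 with a pseudocount of 0.1, 12 with 0.5, 51 without a filter, 11 with a robust prior, and between 14 and 43 with 1 library left out. With 1 library left out, over 1.5 times as many genes were called without knockout library 1 (58 higher), knockout library 2 (30 higher) and wild-type library 1 (43 lower). Without short RNA genes limma called 0 higher and 1 lower. The unfiltered fit shared 10 higher and 5 lower genes with the filtered one. Apart from the removal of short RNA genes, which itself took away 37 of the 38 calls, the cause was not tested. The 7 lists past the threshold became 0 with an estimated correlation and 0 with fry in one direction, and between 5 and 12 with 1 library left out, the 12 without knockout library 2.

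The RNA libraries share replicate numbers, but the labels do not say that a number marks a pair. Deviations of library 1 from the group means correlated at r = 0.209 across genes between genotypes, or 0.349 without short RNA genes, over only 2 pairs. With the replicate number as a block, limma called 22 higher and 22 lower genes and 6 lists. Without short RNA genes and with the block it called 87 higher and 186 lower. Of these 273, 173 were listed by the authors, whose table came from the same libraries, so the overlap is no independent evidence. Arc (limma adjusted p = 3.84e-05), Nr4a1 (5.75e-04), Dusp5 (5.87e-04), Wfs1 (3.79e-05) and Hrh3 (6.27e-07) then passed over all genes, while Hdac3 did not. Whether single genes pass thus depends on a pairing that the labels do not give.

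Signs changed for 5 named genes and 3 lists, with Tsc22d3 (-0.31) the largest of them. Foxo3 (-0.03 on the log2 scale) was 0.0022 with median-ratio rescaling and 0.0174 with quantile normalisation, which also took the pyramidal markers to -0.0173. With 1 library left out the log2 change lay between -0.0709 and 0.0146 for Foxo3, -0.0564 and 0.0706 for Foxo1, -0.269 and 0.0993 for Foxo6, -0.0655 and 0.211 for Ncor1, and -0.839 and 0.213 for Tsc22d3. Medians then lay between -0.277 and 0.244 for pyramidal markers, -0.0504 and 0.0795 for the corepressor complex, and -0.199 and 0.0297 for interneuron markers. The cause was not tested. The other 83 of 88 named genes kept their direction in every alternative run, or 59 of 64 without short RNA genes. Many were named because their replicates were separated. For those genes a library left out or another pseudocount cannot change the sign, so the count is no test of them.

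The share of listed genes with separated replicates was 88.1% and lay between 90.8% and 96.0% with 1 library left out, where fewer libraries make separation easier. The odds ratio of HDAC3 peaks at higher against lower genes lost its call in the lowest (3.97) and middle (1.37) FPKM tertiles and in the middle tertile of locus length (2.56), where fewer genes were compared, and kept it in the other 12 alternatives. The 6150 peaks became 3075 in the upper 50% by score and 3454 at a false discovery rate under 1%, by construction. Peak distances from start sites, peaks at limma genes and the shift of peak genes were not run for want of mm9 gene positions.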

Other observations

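The tests of explanations in this part were all chosen after the results were seen.

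Several genes that respond to interferon, present antigen or respond to glucocorticoids, and that were listed lower, stood highest in wild-type library 2. All 13 interferon and antigen presentation genes listed lower in the authors' deposited table, a group picked from it after the values were seen, had their highest value there, with a median difference of 1.47 on the log2 scale between the 2 wild-type libraries. Gbp4, a guanylate-binding protein, stood at 0.263 and 1.69 FPKM in the wild-type libraries and at 0.261 and 0.267 FPKM in the knockout libraries, and the MHC class I light chain gene B2m at 19.7 and 28.6 against 15.7 and 15.1 FPKM. Of 14 glucocorticoid-responsive genes, a list also made after the values were seen, 13 were highest in wild-type library 2, among them the 5 listed lower. Sgk1 stood at 14.5 and 28.2 FPKM in wild type and at 13.1 and 13.6 FPKM in knockout, and Plin4 at 1.68 and 5.84 against 1.71 and 2.42 FPKM. Exceptions were Per1, the other of the 14, at 4.67 and 5.34 against 5.85 and 5.15 FPKM, and Ifi30, an interferon-inducible gene listed higher, at 0.410 and 0.501 FPKM in wild type and 1.64 and 0.781 FPKM in knockout.

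For the 13 interferon and antigen presentation genes, 2 explanations were set against each other. Since the 13 were picked from genes listed lower, a library that stands apart was tested on the 15 other measured members of the fixed interferon list. Of these, 11 (73.3%) were highest in wild-type library 2, where chance gives 25%, and Isg15, Oas1a, Mx1 and Usp18 were not. Only 7 of the 19 fixed members reached a mean of 1 FPKM, B2m, H2-D1 and H2-K1 of the 13 among them, so most of the 15 were low. The 7 were correlated (estimated correlation 0.76), so members are not independent draws against 25%. If the knockout lowered these genes, most should lie below wild-type library 1 in both knockout libraries, which held for 5 of 13 (38.5%), where chance gives 33.3%. A candidate explanation for the listing of these genes is the state of 1 wild-type sample, while for the 5 genes that were also below wild-type library 1, B2m among them, an effect of the knockout stays open.

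The limma calls on short RNA genes may rest on a few reads. After the value of 1 read was taken out, the 2 libraries of the higher group were equal within 2% in 18 of 37 called short RNA genes, which limma's selection of close replicates favours. Of the 19 with unequal libraries, 15 (78.9%) stood within 2% of another ratio of whole numbers up to 3, against 12.3% when each ratio was spread evenly over neighbouring values. A change of the transcript that carries the microRNA cluster around Mirg stays open: 4 of its 6 called microRNA genes were higher and 2 lower (66.7% in the larger direction), but 4 of the 6 stood at such ratios and the other 2 had equal libraries, so their directions do not decide it. Mirg itself, a long non-coding RNA gene, stood at 5.71 and 6.77 FPKM in wild type and at 9.23 and 8.85 FPKM in knockout (limma adjusted p = 0.560).

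The lower immediate early genes could in principle reflect 1 odd library or a lower share of excitatory neurons. The list median stayed at or below -0.30 whichever of the 4 libraries was left out, which argues against a single library as the whole source. Pyramidal neuron markers had a median log2 change of 0.00105 with an SD over markers of 0.395, and members went both ways, so a lower share of these neurons cannot be told apart from lower transcription within them. By pairs of libraries the median was -0.21 for knockout 2 against wild type 1 and between -0.50 and -0.40 for the other 3 pairs, while it was 0.15 between the 2 wild-type libraries and 0.16 between the 2 knockout libraries. An effect of Hdac3 loss and a difference in the animals' activity before dissection both stay open, as neither was tested.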
